A study of Homo sapiens with 4 samples.

How the data were processed

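RNA of 4 cultures of human CD34+ cells was hybridized to 1 microarray each, 2 arrays for each culture method. Per the labels' protocols the RNA was extracted with a kit that keeps small RNA as well as messenger RNA, and biotin-labelled cRNA was made with a kit for Illumina arrays. The probe identifiers and control probe sets in the table are of an Affymetrix transcript-level array, and the submitters' processing notes name GCOS 4.0, an Affymetrix program, so the labelling protocol and the platform named in the sources do not match. The deposited table holds 1 value per probe set and array on a log scale, taken here as log2. The authors' background correction, summarization, between-array scaling, centring and log base are not given in the sources used here. If the base were not 2, the sizes of all differences would change by one factor while their order and tests would not. Values above 16, which the log2 of a 16-bit scanner cannot reach, show that the deposited values are transformed and not plain log2 intensities. The medians of the 4 columns were 6.65, 6.63, 6.63 and 6.63, and their 5th to 95th percentiles lay within 0.152 of each other, so the values were used as deposited with no further normalization.

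The table has 24351 probe sets. The platform annotation names 17709 of them by 1 gene symbol, 0 by several and leaves 6642 unnamed, of which 2903 are control probe sets. Of the named probe sets 17709 were matched by Entrez identifier to the RefSeq gene table, and 0 symbols changed. No genome build is given for the values, so no coordinates are printed. Named probe sets of Y-linked genes, XIST and TSIX (27 probe sets) were left out of every step. A probe set was kept if at least 2 arrays lay above the 40th percentile of all values in the table, a level of 5.51. The probe set with the highest mean stood for a gene, which gave 10535 genes from 10543 probe sets. The files give no detection calls, so a gene below 5.51 on both arrays of one culture was treated as having only a bound there: the difference is given as at least the mean of the other culture minus 5.51. Where 1 array of a culture lay below the level, the measured difference is given; with that value raised to the level, S100A8, S100A9, IRF8 and IL13RA1 would have 7.20, 6.47, 4.83 and 4.18.

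Differences are G3 minus G1. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) on 2 against 2 arrays, without a block. The experiment number is in the sample titles, and the labels say that it marks a preparation of cells, so the numbers pair the arrays. The deviations of same-numbered arrays from their culture means correlated at 0.169 across genes. The fit with the experiment as a replicate block is given beside a count or call of the text that it changes, including the counts adjusted over a list alone. Nothing in the labels says whether the preparations came from separate donors. The p-values per gene therefore measure the spread between these samples, which may be partly technical. Gene lists were tested with camera (preset correlation 0.01, two-sided), which compares a list with the other genes. With that preset its p rests mainly on the spread over genes at a fixed low correlation. A small p of this test therefore does not measure how well a shift repeats between cultures. The lists were tested again with a correlation estimated from the arrays and with fry. Fry tests whether a list's genes move on balance one way and does not compare them with other genes.

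The 23 lists, the tests and the rule for named genes were fixed before the data were examined. The lists were basophil, mast cell, eosinophil, neutrophil granule, monocyte and macrophage, dendritic cell, MHC class II, stem and progenitor, erythroid, megakaryocyte and platelet, lymphoid, IgE receptor signalling, histamine and lipid mediator, cytokine receptor, chemoattractant receptor, STAT5 target, haematopoietic transcription factor, proliferation, cholesterol synthesis, glycolysis and hypoxia, interferon response, immediate early and stress, and housekeeping. Of the listed genes 29 matched no named probe set. Some genes stand in several lists. The text names the 12 genes with the greatest positive and the 12 with the greatest negative difference among those past the threshold and in the same direction in both experiments. Where fewer passed, places were filled with genes of the same direction in both experiments ranked by the smaller of the 2 differences. Since 0 passed, all 24 places were filled in this way and their values are not calls. The text also names the 4 genes of each list with the greatest absolute difference, and KIT, FLT3, IL3RA, CSF2RB, HDC, FCER1A, MS4A2, CLC and SYK. The rule left out unnamed probe sets, provisional symbols, sex-linked genes and genes whose presence or probe match varies between people. Agreement between the experiments was described by correlations across genes with no p.

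The scripts were tested on simulated data of 10535 genes for the G3 and G1 comparison. By each of 4 sizes 50 genes were changed, some raised and some lowered, in a single draw per setting. With independent arrays, the fit without a block recovered 0%, 2%, 48% and 92% of log2 differences of 1, 2, 4 and 6, and the fit with the block 0% at each size. With part of the variance shared within experiments it recovered 0%, 0%, 58% and 78%, and the fit with the block 0%, 0%, 82% and 96%. With lists raised by 1, camera with the preset correlation called 100 of 100 raised lists and 7 of 240 others, and camera with an estimated correlation called 0 of 100 and 0 of 240. The simulated genes varied independently of one another. These runs therefore cannot show how often the preset correlation gives false calls where the genes of a list vary together. Lists raised by more than 1 were not simulated.

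Alternatives were quantile normalization, arrays centred on their medians, no filter and a stricter filter (60th percentile, 7.90), an offset of 50 on the linear scale, the mean over a gene's probe sets, the replicate block, each array left out, other variance priors, thresholds and tests, and single probe sets in place of genes. Scaling arrays on the mean of 4 poly-A control probe sets, which report RNA added before labelling, was added after seeing the data. These controls were higher on the G3 than on the G1 array by 0.30 ± 0.12 (SD, n = 4 controls) in experiment 1 and by 0.62 ± 0.28 in experiment 2, so this scaling moves the median of all G3 minus G1 differences from -0.07 to -0.53, a shift of -0.46. Figures were drawn with matplotlib 3.10.9.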

Results

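Gene expression was measured on 4 microarrays of human CD34+ progenitor cells that had been grown in culture, in a series whose title names basophils derived from such cells. CD34 marks blood stem and progenitor cells, and interleukin-3 (IL-3) is a growth factor that drives them towards basophils. The G1 cultures received IL-3 alone at 5 ng/ml. The G3 cultures received IL-3 at 5 ng/ml with stem cell factor (SCF) at 4 ng/ml and Flt3 ligand (Flt3L) at 8 ng/ml, a pair of cytokines that act on early progenitors through the receptors KIT and FLT3. Each of 2 experiments, which the labels describe as separate cell preparations, gave 1 G1 and 1 G3 array, so each culture method had 2 arrays. The sample titles carry D17, which the labels do not explain, and the cells were resting. The number of arrays limits the precision of every value. The median log2 signal lay between 6.63 and 6.65 on the 4 arrays, and 10535 genes passed the filter on dim probe sets.

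The first comparison asks how the 2 culture methods differ in the cells they give. Of 42 measured genes of neutrophil granules, monocytes and dendritic cells, 34 were higher in the G3 culture in both experiments. The 3 lists passed the list test with a preset correlation, while adjusted p = 0.554 with an estimated correlation for each, and 0 of the genes passed the test over all genes without a replicate block. The signal of MPO, the myeloperoxidase of neutrophil and monocyte granules, was 15.98 ± 1.05 (SD, n = 2) in G3 and 8.12 ± 1.35 (SD, n = 2) in G1 on the log2 scale. Over the neutrophil granule list the mean difference between G3 and G1 was 3.78, with 4.02 in experiment 1 and 3.53 in experiment 2. Genes of cell division had a mean difference of -1.20 over 26 genes, which were lower in G3 in both experiments (adjusted p = 7.88e-15 with the preset correlation, and adjusted p = 0.554 with an estimated correlation). Basophil genes went opposite ways in the 2 experiments, lower in G3 for 13 of 14 genes in experiment 1 and higher for 14 of 14 in experiment 2.

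In the neutrophil granule list, 9 of 12 measured genes were higher in G3 in both experiments and 2 were lower in both. The 2 were the granule protease CTSG (-0.21 in experiment 1 and -0.78 in experiment 2) and LCN2 (-0.30 and -2.40). LCN2 lay below the filter level on both arrays of experiment 1. The list names 20 genes, and ELANE, BPI, LTF, CAMP and MMP8 are among those not counted as measured. Such genes either had no named probe set or did not pass the filter on dim probe sets. The list was shifted upwards relative to the other genes (camera with a preset correlation, adjusted p = 4.6e-13; adjusted p = 0.554 with an estimated correlation). Adjusted over the list alone, 8 of its genes differed (9 with the replicate block), against 0 adjusted over all genes tested (5 with the block). S100A8 and S100A9, the calcium-binding pair abundant in neutrophils and monocytes, differed by 7.54 ± 1.17 and 6.74 ± 0.88 (log2 difference ± SE). PRTN3, the granule protease proteinase 3, was below the filter level on both G1 arrays and was higher in G3 by at least 6.47 on the log2 scale. AZU1, the granule protein azurocidin, had a difference of 4.96 ± 0.61.

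The monocyte and macrophage list had a mean difference of 2.49 (2.41 in experiment 1 and 2.56 in experiment 2), and 16 of its 18 measured genes were higher in G3 in both experiments. Its adjusted p was 4.08e-13 with the preset correlation, and adjusted p = 0.554 with an estimated correlation. Adjusted over the list alone 7 genes differed, and 0 over all genes; with the replicate block these counts were 15 and 1. VCAN, the matrix proteoglycan versican, was higher in G3 by at least 5.94. CD14, the lipopolysaccharide co-receptor of monocytes, differed by 4.08 ± 0.99, and MRC1, the macrophage mannose receptor, by 4.11 ± 0.80. The chemokine CCL2 differed by 4.33 ± 0.62.

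The dendritic cell list had a mean difference of 1.97 (1.78 and 2.17 in experiments 1 and 2), with 9 of 12 genes higher in both experiments, an adjusted p of 6.92e-09 with the preset correlation, and adjusted p = 0.554 with an estimated correlation. Adjusted over the list alone 6 genes differed, with or without the replicate block, and 0 over all genes (2 with the block). IRF8, a transcription factor of monocyte and dendritic cell development, differed by 5.29 ± 1.06. The lipid-presenting molecule CD1C and the lectin CLEC10A were higher in G3 by at least 3.71 and at least 3.09. Not higher in both experiments were XCR1 (-0.45 and -0.08), CLEC9A (-0.34 and 0.07) and CLEC4C (-0.31 and 2.62). BATF3 and CD83, counted as higher in both, had mean differences of only 0.18 and 0.23. FLT3, the receptor of one of the added cytokines, differed by 3.44 ± 0.56, with 2.74 in experiment 1 and 4.13 in experiment 2. The MHC class II list, genes that present antigen to T cells, had a mean difference of 1.58, with 6 of 7 genes higher in both experiments (adjusted p = 1.3e-05, and adjusted p = 0.554 with an estimated correlation). HLA-DPB1 differed by 2.12 ± 0.87, HLA-DPA1 by 1.86 ± 0.85, CD74, the invariant chain, by 1.89 ± 0.66, and CIITA, the regulator of class II transcription, by 1.71 ± 0.68. In that list 0 genes passed adjusted over the list alone and 0 over all genes, and with the replicate block 6 of the 7 passed over the list alone. Without the G3 array of experiment 1 the mean of the MHC class II list was 0.85.

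**Figure D1:**
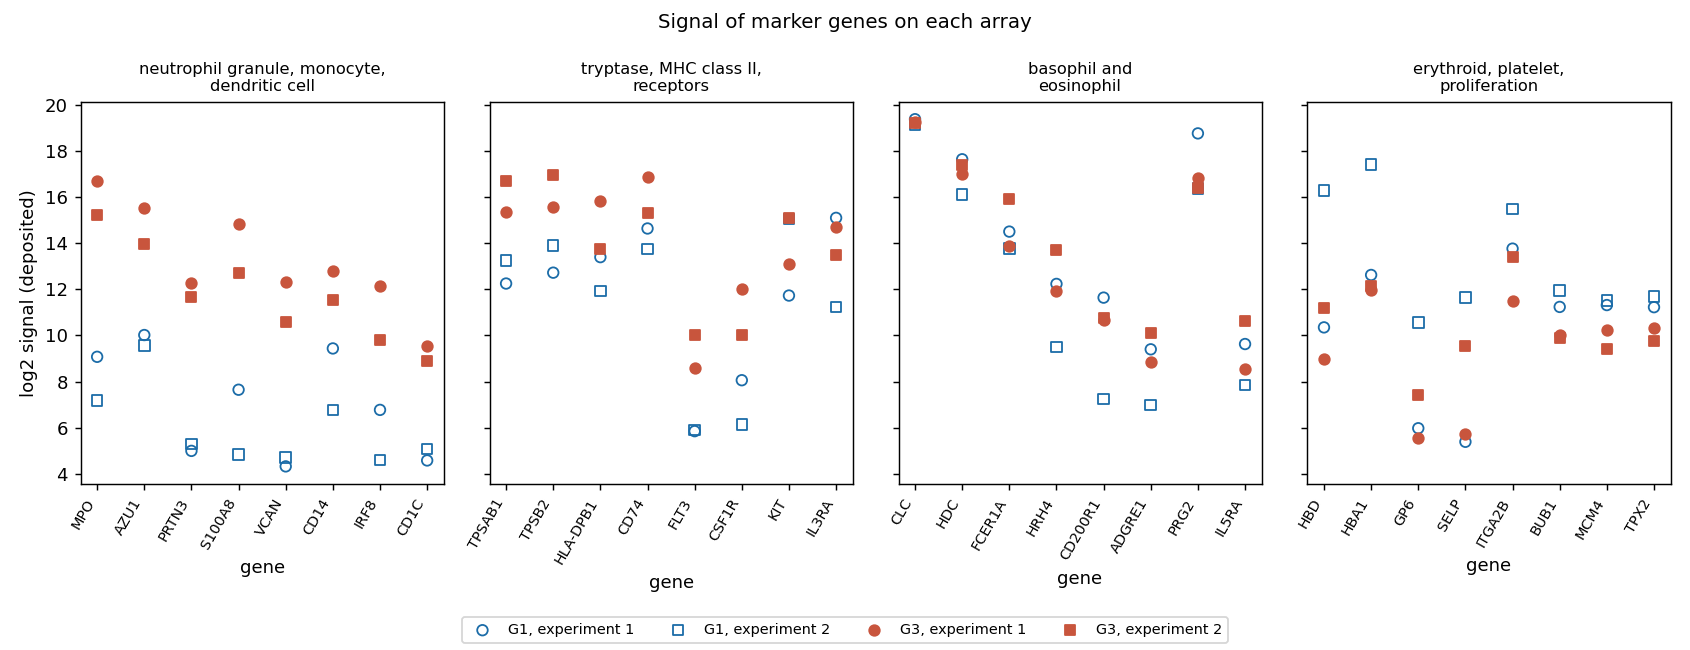
Deposited log2 signal (vertical axis) of marker genes (horizontal axis) on each of the 4 arrays, open symbols for G1, filled for G3, circles for experiment 1 and squares for experiment 2. Both G3 arrays lie above both G1 arrays for MPO, PRTN3, VCAN and FLT3; CLC lies near the highest value of each array, so its points cannot show whether it differs.

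The cytokine receptor list was higher in G3 by a mean of 1.23, with 0.52 in experiment 1 and 1.94 in experiment 2, and 11 of its 21 genes were higher in both experiments (adjusted p = 8.78e-06 with the preset correlation, and adjusted p = 0.554 with an estimated correlation). Adjusted over the list alone 1 gene differed (5 with the replicate block), and 0 over all genes. Beside FLT3, the genes with the greatest differences were IL13RA1, a receptor chain for IL-13, at 4.47 ± 1.01, CSF1R, the receptor of macrophage colony-stimulating factor, at 3.92 ± 0.94, and CSF3R, that of granulocyte colony-stimulating factor, at 2.54 ± 0.92. KIT, the SCF receptor, had a difference of 0.72 ± 1.27. IL3RA and CSF2RB, the chains of the IL-3 receptor, had differences of 0.94 ± 1.33 and 0.42 ± 0.69, and CSF2RB turned to -0.04 when arrays were scaled on the poly-A controls. Without the G1 array of experiment 2 the mean of this list was 0.62, IL3RA had -1.01 and CSF2RB -0.49. KIT turned to -0.94 without the G1 array of experiment 1 and to -0.29 without the G3 array of experiment 2. The chemoattractant receptor list had a mean difference of 1.26 (0.18 and 2.34), with 7 of 12 genes higher in both experiments, an adjusted p of 4.83e-05, and adjusted p = 0.554 with an estimated correlation. Of these, 0 passed adjusted over the list alone (2 with the replicate block) and 0 over all genes. CCR2 and CCR1, chemokine receptors of monocytes, differed by 3.29 ± 1.07 and 2.58 ± 0.70, and C3AR1, the receptor of complement C3a, by 1.89 ± 0.80. Without the G1 array of experiment 2 the mean of this list was 0.29 and its adjusted p 0.0717, and without the G1 array of experiment 1 the mean was 2.23.

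The mast cell list had a mean difference of 1.04, with 0.41 (SE 0.35 over genes) in experiment 1 and 1.67 in experiment 2. Of its 16 genes, 8 were higher in G3 in both experiments (adjusted p = 1.3e-05 with the preset correlation, and adjusted p = 0.554 with an estimated correlation). These were TPSAB1, TPSB2, TPSD1, TPSG1, KIT, MITF, VWA5A and CMA1. The other 8 were lower in experiment 1, while 15 of the 16 were higher in experiment 2. SIGLEC6, CPA3 and IL1RL1, for example, had -1.16, -0.88 and -0.59 in experiment 1 and 2.33, 0.67 and 2.22 in experiment 2. The greatest values of experiment 1 were those of TPSAB1 (3.09) and TPSB2 (2.85). Adjusted over the list alone 3 genes differed (4 with the replicate block), and 0 over all genes. The greatest differences were those of 3 tryptases, proteases stored in mast cell granules. TPSAB1 differed by 3.27 ± 0.62, with 3.09 in experiment 1 and 3.46 in experiment 2. TPSB2 differed by 2.96 ± 0.66 and TPSD1 by 2.13 ± 0.48, and VWA5A by 1.86 ± 0.55. TPSAB1 and TPSB2 are near-identical copies, so their probe sets may read each other's transcripts and their values are uncertain as separate measurements. Signal shared with the probe set of TPSD1 cannot be excluded. Without the G3 array of experiment 2 the mean of the mast cell list was 0.64.

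The proliferation list was lower in G3 in both experiments for 26 of its 26 genes, with mean differences of -0.70 in experiment 1 and -1.70 in experiment 2. It was shifted downwards relative to the other genes (adjusted p = 7.88e-15 with the preset correlation, and adjusted p = 0.554 with an estimated correlation), while 0 single genes passed adjusted over the list alone and 0 over all genes. CDC20, BUB1 and TPX2, which act in mitosis, had differences of -1.71 ± 0.83, -1.65 ± 0.39 and -1.42 ± 0.39, and MCM4, a subunit of the replicative helicase, -1.59 ± 0.42. The erythroid list had a mean difference of -2.50, with -0.91 in experiment 1 and -4.09 in experiment 2, and 8 of 8 genes were lower in G3 in both (adjusted p = 0.00214, and adjusted p = 0.554 with an estimated correlation). Of the erythroid genes 0 passed adjusted over the list alone and 0 over all genes, and with the replicate block 8 of 8 passed over the list alone. The globin genes HBD, HBA1 and HBA2 had differences of -3.23 ± 2.04, -2.95 ± 1.56 and -2.83 ± 1.63, and CA1, a carbonic anhydrase of red cells, -2.67 ± 1.88. HBA1 and HBA2 are near-identical copies and cannot be read as separate measurements. The G1 array of experiment 2 carried the high erythroid signal, with a list mean 4.46 above that of the G1 array of experiment 1. Without it the mean difference was -0.27 and the adjusted p 0.381, and CA1 had a difference of 0.15, while without the G1 array of experiment 1 the mean was -4.72 (adjusted p = 1.65e-09).

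Genes of cholesterol synthesis had a mean difference of -0.58 (-0.13 and -1.03), with 9 of 15 lower in both experiments, an adjusted p of 0.0189, and adjusted p = 0.647 with an estimated correlation. MSMO1 had a difference of -1.28 ± 0.65 and HMGCS1 of -0.99 ± 0.67, while LSS and MVD both had -0.98, with SE 0.57 and 0.48. Without the G3 array of experiment 2 the list mean was -0.08 with adjusted p = 0.925, without the G3 array of experiment 1 it was -1.08, without the G1 array of experiment 1 it was -0.53 with adjusted p = 0.171, and with arrays scaled on the poly-A controls it was -1.04 with adjusted p = 0.0734. Immediate early and stress genes had a mean difference of 0.42 (-0.09 and 0.94), with 6 of 15 higher in both, an adjusted p of 0.0247, and adjusted p = 0.554 with an estimated correlation. When arrays were scaled on the poly-A controls the list was still shifted relative to the other genes (camera with the preset correlation, adjusted p = 0.0118), while its mean turned to -0.04. Without the G1 array of experiment 2 it was -0.10 with adjusted p = 0.990, without the G1 array of experiment 1 it was 0.94, and without the G3 array of experiment 2 it was 0.43 with adjusted p = 0.0612. TXNIP differed by 1.29 ± 0.90 and turned to -0.04 without the G1 array of experiment 2. JUN lay below the filter level on that array and between 5.68 and 5.70 on the others, and its difference was 0.08 with that value raised to the level. FOS differed by 0.85 ± 0.44 and DDIT4 by 0.83 ± 0.39. In both lists 0 genes passed adjusted over the list alone and 0 over all genes.

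**Figure D2:**
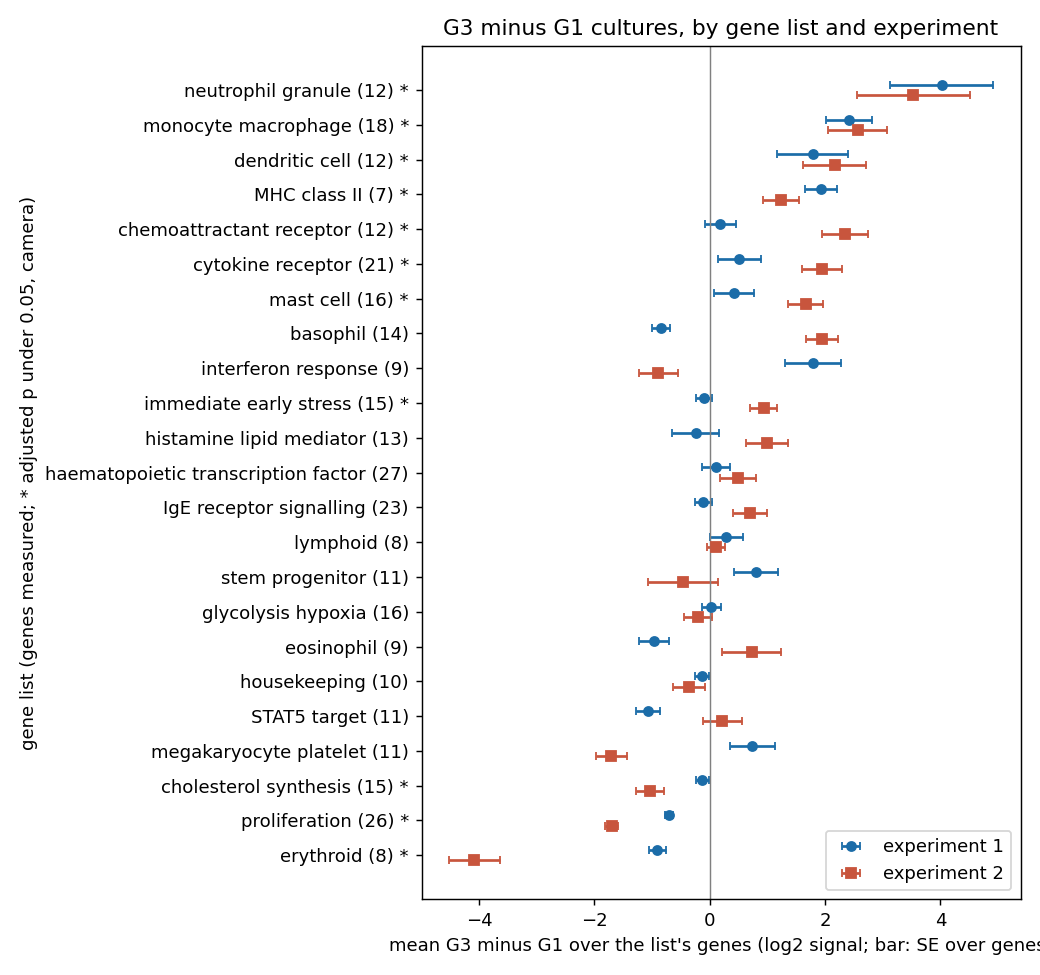
Mean G3 minus G1 difference in log2 signal (horizontal axis) over the measured genes of each of the 23 lists (vertical axis), as circles for experiment 1 and squares for experiment 2, with bars of 1 SE over genes. The neutrophil granule list lies at 4.02 and 3.53 and the erythroid list at -0.91 and -4.09, and the basophil list lies on opposite sides of 0 in the 2 experiments. An asterisk marks 11 lists with adjusted p under 0.05 in the camera test with a preset correlation. With poly-A scaling the immediate early mean turns to -0.04, while that list still passes this camera test (adjusted p = 0.0118). With an estimated correlation 0 lists passed, the smallest adjusted p of camera being 0.554. That setting also called 0 of 100 simulated lists raised by 1.

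The basophil list, by contrast, went opposite ways in the 2 experiments. In experiment 1, 13 of its 14 genes were lower in G3, with a mean of -0.84, and in experiment 2, 14 of 14 were higher, with a mean of 1.94. Its mean over both was 0.55 (adjusted p = 0.0607; 0.0384 with the replicate block, where adjusted p = 0.804 with an estimated correlation), and 0 genes passed adjusted over the list alone. Without the G1 array of experiment 2, which also carried the high erythroid signal, the mean was -0.39. Without either array of experiment 1 the list passed, with a mean of 1.49 without G1 (adjusted p = 3.2e-05) and 1.01 without G3 (adjusted p = 0.000398). It also passed with the stricter filter (adjusted p = 0.0443) and with poly-A scaling (mean 0.09, adjusted p = 0.00465). The receptors HRH4 for histamine, CD200R1 and IL3RA had -0.31, -0.96 and -0.38 in experiment 1 and 4.23, 3.54 and 2.25 in experiment 2, and the transcriptional regulator LMO4 had 0.12 and 2.71. FCER1A, the IgE-binding chain of the high-affinity IgE receptor, stood at 14.90 ± 1.43 in G3 and 14.15 ± 0.51 in G1 (SD, n = 2 each), and its difference turned to -0.26 without the G3 array of experiment 2. HDC, which makes histamine, stood at 17.21 ± 0.30 in G3 and 16.89 ± 1.08 in G1, with -0.65 in experiment 1 and 1.29 in experiment 2. Its mean difference of 0.32 ± 0.59 turned to -0.14 with poly-A scaling and to -0.44 without the G1 array of experiment 2. CLC, the Charcot-Leyden crystal protein, read 19.39 and 19.13 on the G1 arrays and 19.25 and 19.24 on the G3 arrays, close to the arrays' highest values (19.29 to 19.39), so its signal may be saturated and no difference is read from it. The counts and means of the basophil and eosinophil lists still include it, with -0.14 in experiment 1 and 0.11 in experiment 2. For MS4A2, the beta chain of the IgE receptor, no probe set was named.

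The eosinophil list had a mean of -0.12 (-0.97 in experiment 1 with 9 of 9 genes lower, 0.72 with an SE of 0.51 over genes in experiment 2 with 7 of 9 higher; adjusted p = 0.924). PRG2, the eosinophil major basic protein, had -1.92 in experiment 1 and a difference near 0 in experiment 2, and IL5RA had -1.10 and 2.78. Without the G1 array of experiment 2 this list passed with a mean of -0.65 (adjusted p = 0.0285), while its mean turned to 0.40 and 0.20 without the G1 or the G3 array of experiment 1. The macrophage and eosinophil receptor ADGRE1 had a difference of 1.31 ± 0.92, with -0.53 in experiment 1 and 3.15 in experiment 2. The transcription factor GATA1 had -1.56 ± 0.68, with -1.09 in experiment 1 and -2.02 in experiment 2. The megakaryocyte and platelet list had a mean of -0.49 (0.74 and -1.71; adjusted p = 0.759). ITGA2B, the platelet integrin chain, had -2.19 ± 0.88, GP6, the platelet collagen receptor, -1.78 ± 1.61, SELP -0.87 ± 2.35 and TREML1 0.72 ± 0.55. This list stood 4.92 higher on the G1 array of experiment 2 than on the G1 array of experiment 1, and without the former its mean turned to 1.98 (adjusted p = 1.17e-06), with 0.51 for GP6 and 2.26 for SELP. The mean was -2.95 without the G1 array of experiment 1 (adjusted p = 3.98e-05), -1.72 without the G3 array of experiment 2 (adjusted p = 0.0378) and 0.75 without the G3 array of experiment 1. Interferon-response genes had a mean of 0.45 (1.79 in experiment 1 with 9 of 9 genes higher, -0.89 in experiment 2 with 8 lower; adjusted p = 0.329). IFI6, XAF1 and IFI44 had 3.93, 2.78 and 3.80 in experiment 1 and -0.86, 0.14 and -0.93 in experiment 2, and IFI27 had 0.75 and -3.22. The mean of this list turned to -0.67 without the G3 array of experiment 1 (adjusted p = 0.0230) and to -0.01 with poly-A scaling. It was 1.57 without the G3 array of experiment 2 (adjusted p = 7.42e-08) and 1.22 with no filter (adjusted p = 0.0248). In these 3 lists 0 genes passed adjusted over the list alone, and with the replicate block 1 megakaryocyte gene did.

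The other lists were not shifted by the camera test with the preset correlation. The stem and progenitor list had a mean of 0.17 but a median of -0.35 (adjusted p = 0.524), with FLT3 as its 1 gene adjusted over the list alone (2 genes with the replicate block). Without the G1 array of experiment 2 its mean was 0.97 (adjusted p = 0.000776), and without the G1 array of experiment 1 it was -0.64. PROM1 was higher in G3 by at least 1.81, and MLLT3 and MEIS1 had -1.40 ± 1.14 and -1.19 ± 1.57. The STAT5 target list had a mean of -0.42 (-1.06 and 0.22; adjusted p = 0.236), with -1.19 ± 0.76 for CISH, -1.05 ± 1.02 for MYC, -0.85 ± 0.64 for OSM and -0.65 ± 0.37 for BCL2L1. It passed without the G1 array of experiment 2, with a mean of -0.93 (adjusted p = 0.000103), and with no filter (adjusted p = 0.0319), and its mean was 0.08 without the G1 array of experiment 1. The IgE receptor signalling list lay close to the threshold, with a mean of 0.29 (adjusted p = 0.0579). It passed with quantile normalization (adjusted p = 0.0362), the stricter filter (adjusted p = 0.0430) and the offset (adjusted p = 0.0459). Its mean was 0.52 without the G1 array of experiment 1 and 0.46 without the G3 array of experiment 1 (adjusted p = 0.0156 in both), 0.06 without the G1 array of experiment 2 and 0.12 without the G3 array of experiment 2. Its kinase SYK had a difference of 0.21 ± 0.37, which turned to -0.25 with poly-A scaling and to -0.06 without the G3 array of experiment 1. The exchange factor SOS1 had -2.13 ± 0.94, the inhibitory receptor CD300A 1.98 ± 0.71, CBL 1.41 ± 0.58 and PLCG2 1.10 ± 0.82. The histamine and lipid mediator list had a mean of 0.38 (adjusted p = 0.0946), with HNMT, which breaks down histamine, at 2.54 ± 0.33 as its 1 gene adjusted over the list alone, and HPGDS at 1.53 ± 0.76, LTA4H at 1.33 ± 0.89 and PTGS1 at -1.28 ± 0.75. It passed with the stricter filter (adjusted p = 0.0481), without the G1 array of experiment 1 (mean 0.68, adjusted p = 0.0258) and without the G3 array of experiment 1 (mean 0.70, adjusted p = 0.00691). Its mean was 0.08 without the G1 array of experiment 2 and 0.05 without the G3 array of experiment 2. The haematopoietic transcription factor list had a mean of 0.30 (adjusted p = 0.108), with NFIL3 at 1.77 ± 0.95 and ID2 at 1.36 ± 0.40 behind IRF8, which passed with the replicate block. Without the G3 array of experiment 1 its mean was 0.46 (adjusted p = 0.0156). The lymphoid list had a mean of 0.20 (adjusted p = 0.289), with IL7R at 1.01 ± 0.43, CD3E at least 0.53 higher, CD79A at -0.42 ± 0.35 and NKG7 at -0.38 ± 0.97. With poly-A scaling the means of the stem, IgE, histamine, transcription factor and lymphoid lists turned to -0.29, -0.17, -0.08, -0.16 and -0.26, and the IgE, histamine and transcription factor lists were shifted upwards relative to the other genes (adjusted p = 0.0214, 0.0228 and 0.0487). The glycolysis and hypoxia list had a mean of -0.09 (adjusted p = 0.996), with ADM at least 0.84 higher and SLC2A1, TPI1 and ALDOC at -1.08, -1.04 and -0.85. The housekeeping list had a mean of -0.25 (adjusted p = 0.289), with HPRT1, GUSB, B2M and PPIA at -0.97, -0.76, 0.63 and -0.58, B2M turning to -0.17 without the G1 array of experiment 2.

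Across all genes, the naming rule took those with the greatest differences in the same direction in both experiments. On the higher side, beside the genes above, these were FGL2 (5.76 ± 0.95), IL1R2, the decoy receptor of interleukin-1 (at least 3.70), MPEG1, a pore-forming protein of macrophages (5.82 ± 1.20), the low-affinity IgE receptor FCER2 (4.85 ± 0.37) and LY86 (5.47 ± 1.32). On the lower side were CD24, a surface protein of immature blood cells (-4.06 ± 1.40), RHAG and ANK1, membrane proteins of red cells (-4.05 ± 2.15 and -3.21 ± 2.31), OPN3 (-3.31 ± 1.53), CHML (-2.66 ± 0.73), the exporter ABCC4 (-2.39 ± 0.72), PRSS57, a serine protease of myeloid granules (-2.33 ± 0.39), and the potassium channel KCNK5 (-2.27 ± 0.32). ANXA3, MLLT11 and ITGA2B had -2.13 ± 0.33, -2.08 ± 0.33 and -2.19 ± 0.88. KDELR3 was below the filter level on both G3 arrays and had a difference of -1.29 or lower. The sizes for RHAG, ANK1, CD24 and OPN3 depend on single G1 arrays. RHAG and ANK1 read 7.29 and 9.49 on the G1 array of experiment 1 and 13.55 and 15.54 on that of experiment 2. CD24 and OPN3 read 15.44 and 15.14 on the former and 11.2 and 10.77 on the latter.

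In the test per gene (limma), 0 of 10535 genes had an adjusted p under 0.05, the smallest being 0.109 for PRTN3, and 664 had an unadjusted p under 0.05, with 318 higher and 346 lower in G3, where 527 would be expected by chance if arrays of one experiment shared no spread, and fewer if they did. With the experiment as a replicate block, 16 genes passed, all of them higher in G3 in both experiments, and 735 had an unadjusted p under 0.05. These were MPO and S100A8 (both with adjusted p = 0.0152 in the blocked limma fit), PRTN3, S100A9, FGL2, IRF8, VCAN, FCER2, IL1R2, AZU1 and CLEC10A, and 5 genes outside the naming rule, named after their values were seen: RGL1 (4.83), TGFBI (4.72), GLIPR1 (4.61), SAMHD1 (4.44) and EPB41L3 (4.25). The count depended on single arrays, with 379 genes without the G1 array of experiment 1 and 8 without the G1 array of experiment 2. Of the 23 lists, 11 were shifted by camera with the preset correlation, 8 upwards and 3 downwards. With arrays scaled on the poly-A controls 14 were shifted, 12 of them upwards, and with the replicate block 12 were shifted. The preset test also called 14 lists in the split that crosses culture and experiment. With an estimated correlation or by fry 0 were shifted. In the simulation the estimated correlation called 0 of 100 lists raised by 1, so its 0 says little about shifts of that size. The power of fry was not simulated.

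The second comparison asks how far the 2 experiments gave the same difference between cultures. Across the 10535 genes the differences of experiment 1 and experiment 2 had a Pearson correlation of 0.253 and a Spearman correlation of 0.0746, and 52.0% of genes had the same sign; genes are not independent replicates, so no p is given. By at least 2 on the log2 scale, 187 genes were higher in G3 in experiment 1 and 422 in experiment 2. These lists shared 107 genes, where independent lists would share 7.49, and 5 were higher by that much in experiment 1 and lower by it in experiment 2. Lower by at least 2 were 47 genes in experiment 1 and 394 in experiment 2, with 8 in both, against 1.76 for independent lists. The differences spread more widely in experiment 2 (SD 1.14 across genes) than in experiment 1 (SD 0.731).

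**Figure D3:**
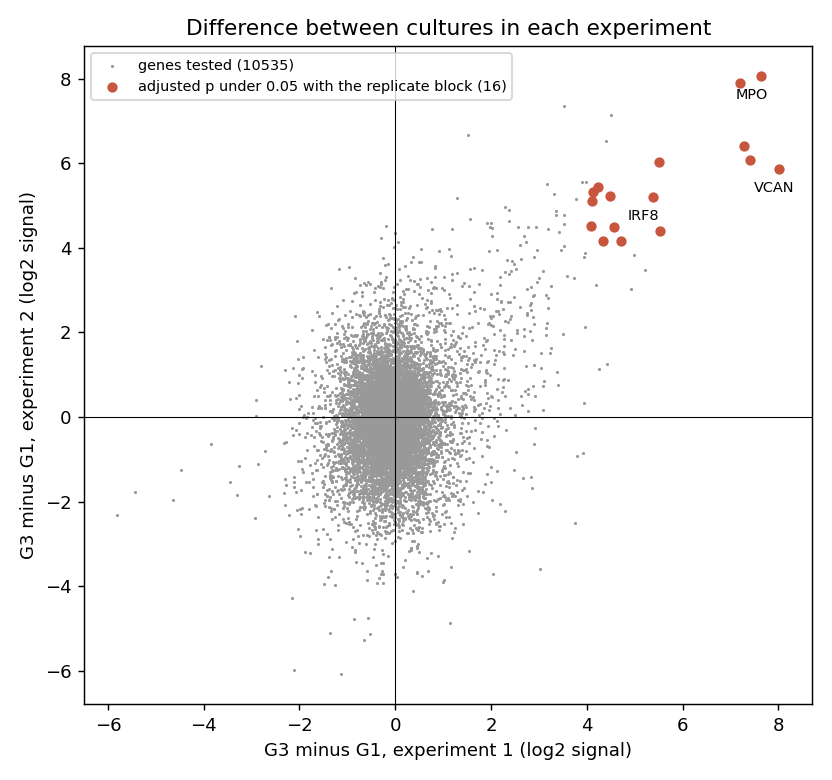
G3 minus G1 difference in log2 signal of each of 10535 genes in experiment 1 (horizontal axis) and experiment 2 (vertical axis). The 16 larger points are the genes with adjusted p under 0.05 in the fit with the replicate block, which all lie above 4 in both experiments.

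The third comparison, between the experiments with the culture method in the model, measures how much the preparations differed. Megakaryocyte and platelet genes stood higher in experiment 2 by a mean of 3.70, with 4.92 between the G1 arrays and 2.47 between the G3 arrays. Erythroid genes stood higher in experiment 2 by 2.87, with 4.46 between the G1 arrays and 1.28 between the G3 arrays. Monocyte and macrophage genes stood lower in experiment 2, with a mean of -0.94. In limma, 0 genes had an adjusted p under 0.05 and 638 an unadjusted p under 0.05, and 12 of the 23 lists were shifted by camera with the preset correlation (adjusted p = 1.23e-20, 7.11e-11 and 1.96e-08 for the lists above; adjusted p = 0.850 for each with an estimated correlation). The G1 array of experiment 2 stood apart from the rest, since its log2 differences from the other 3 arrays had SDs of 1.10, 1.20 and 1.14 across genes, against 0.675 to 0.798 among those 3.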

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

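Tests in this part were chosen after the results were seen, except the count over splits of the arrays, which was planned.

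The means of the basophil and eosinophil lists went opposite ways in the 2 experiments. The G3 minus G1 mean of the basophil list was 2.79 greater in experiment 2 than in experiment 1, and that of the eosinophil list 1.69 greater; with 1 array per culture and experiment the difference was not tested. A weak hybridization of the G1 array of experiment 2 as the whole cause was not settled. Its hybridization control furthest from the mean of the other arrays lay 0.143 above that mean in the deposited values. The medians of the arrays lay between 6.63 and 6.65, and the authors' scaling is not known. A scaling that matched the arrays would raise dimmed controls along with dimmed genes, so the controls cannot decide. The 22 genes of both lists lay below genes of like signal between the G1 arrays by -1.54 (SE 0.285 over genes). That value cannot decide either, since the lists were picked for a reversal in which the low values on this array take part. Dilution of basophil RNA by a common factor in the G1 culture of experiment 2 was not settled. The 11 basophil genes measured between 5.51 and 15 on both G1 arrays differed between them by a mean of -1.87 with an SD of 1.17. Their differences ran from -0.57 (LMO4) to -4.41 (CD200R1), where a common factor alone would give equal ones. The SD lay at percentile 77.3 of 10000 random lists of other genes of that range. The spread of such lists holds differences between the 2 cultures as well as measurement error, so this percentile cannot decide. With 1 array per culture and experiment the measurement error is not known. Cells of other types in the G1 culture of experiment 2 may account for part of the opposite directions. Its erythroid and megakaryocyte lists stood 4.46 and 4.92 above those of the other G1 array. A difference between the preparations stays open and untested.

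The megakaryocyte and platelet list also changed direction, with a G3 minus G1 mean lower in experiment 2 than in experiment 1 by a difference of -2.45. The interferon-response list did so by -2.68. Neither difference was tested.

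Among 3689 probe sets without a gene name that are not controls, 2030 passed the filter, and 8 were higher in G3 by at least 2 in both experiments while 2 were lower. In limma, 0 of them had an adjusted p under 0.05 and 131 an unadjusted p under 0.05.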

How the results depend on the processing

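Poly-A scaling was added after seeing the data. The count of 0 genes differing between cultures held under quantile normalization, median centring, both filters, the offset, the mean over probe sets, poly-A scaling, other variance priors, both thresholds, the plain test and single probe sets. It became 16 with the replicate block, and ran from 0 to 379 with an array left out (379 without the G1 array of experiment 1, 8 without the G1 array of experiment 2, 0 without either G3 array). The lone array is then assumed to vary like the other culture. The replicate block changed 1 list's call, that of the basophil list. With all arrays kept, the count of 11 lists stayed between 11 and 14 except with an estimated correlation (0) and fry (0, with 3 at an unadjusted p under 0.05). The called lists were not always the same. With poly-A scaling 9 of the 11 kept both their call and the sign of their mean. With an array left out the mean of the erythroid list ran from -4.72 to -0.27 and that of the cholesterol synthesis list from -1.08 to -0.08. The correlation between experiments stayed between 0.218 and 0.263. The count of 0 genes between experiments became 8 with the stricter filter. It was 0 under quantile normalization, median centring, no filter, the offset, the mean over probe sets and poly-A scaling. Other variance priors, thresholds and tests and single probe sets were not run for it. With an array left out that model has no residual degrees of freedom and was not run. The cause was not tested for any of these.

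Directions turned as follows. With quantile normalization CLC, whose signal lies near the top of every array, had 0.10. With poly-A scaling CSF2RB, HDC and SYK had -0.044, -0.14 and -0.25, and the stem, lymphoid, IgE, histamine, transcription factor, interferon and immediate early lists -0.29, -0.26, -0.17, -0.084, -0.16, -0.012 and -0.037. With an array left out the values ran as follows, PRG2 -2.16 to 0.23, NKG7 -1.44 to 0.67, OSM -1.73 to 0.019, KIT -0.94 to 2.38, CLC -0.15 to 0.11, eosinophil list -0.65 to 0.40, stem progenitor list -0.64 to 0.97, stat5 target list -0.93 to 0.083, SELP -4.00 to 2.26, IFI6 -0.90 to 3.97, XAF1 -0.011 to 2.93, IFI44 -0.60 to 3.48, SYK -0.064 to 0.49, megakaryocyte platelet list -2.95 to 1.98, interferon response list -0.67 to 1.57, CD200R1 -0.92 to 3.50, IL3RA -1.01 to 2.88, IL5RA -0.21 to 1.89, MLLT3 -3.06 to 0.26, MEIS1 -3.31 to 0.93, CA1 -5.49 to 0.15, GP6 -4.07 to 0.51, PLCG2 -0.074 to 2.28, MYC -2.57 to 0.47, IFI27 -2.68 to 0.20, TXNIP -0.042 to 2.62, JUN -0.016 to 2.59, B2M -0.17 to 1.43, CSF2RB -0.49 to 1.32, HDC -0.44 to 1.08, basophil list -0.39 to 1.49, immediate early stress list -0.10 to 0.94, FCER1A -0.26 to 1.76, glycolysis hypoxia list -0.28 to 0.10. The signal over background is not given in the table, so values near 5.51 are least certain.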

Other observations

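The tests in this part were chosen after the results were seen, apart from the count over splits of the arrays.

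The neutrophil granule, monocyte and dendritic cell genes were higher in G3 in both experiments. A scaling difference between arrays is argued against, since with poly-A scaling the smallest mean of the 3 lists in either experiment was still 1.48, where the SE of the shift was at most 0.139. A lower share of the main cell type alone, which would raise the markers of every other type alike, is argued against by the erythroid list, which lay below the neutrophil granule list by -4.93 (SE 0.911 over genes) in one experiment and by -7.62 in the other. A hypothesis is that cells of these types were present in the G3 cultures. Of the 42 members of the 3 lists, 34 (81.0%) were higher in both experiments. That lies between limits of 50% and 90%, which were set once the values were known. A change within the main cells would raise this share as well, so it cannot tell the 2 explanations apart, and both stay open. Chance cannot be weighed with so few arrays: the 3 splits into 2 and 2 cannot give a share under 0.05, and 2 of them gave at least 11 shifted lists, the highest other being 14 in the split that crosses culture and experiment.

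The tryptase genes TPSAB1, TPSB2, TPSD1 and TPSG1 were higher in G3 in both experiments, TPSG1 by 1.01 and 0.33. More mast cells in G3 is a candidate explanation that stays open, since 3 of 5 other mast cell genes measured below a level of 13 on the G1 arrays (60%) were higher in both experiments. The 3 were MITF, VWA5A and CMA1, and the others were CTSG and LTC4S. The level left out CPA3, HPGD, HPGDS, IL1RL1, SIGLEC6 and SLC18A2, which were lower in G3 in experiment 1 and higher in experiment 2. It also left out KIT, which was higher in both, so the share depends on the level chosen. CMA1 lay below the filter level on both G1 arrays and was higher by at least 0.17 only. SCF, the mast cell growth factor, is in G3 alone, but the design does not separate it from Flt3L. Signal shared between the probe sets of TPSAB1 and TPSB2 stays open too: their differences lay 0.378 and 0.242 apart in the 2 experiments, neither as close as 0.1 nor as far as 0.5. That comparison replaced, after its outcome was seen, one over the 4 tryptase genes that argued against shared signal, with differences spanning 2.07 and 3.13, because it rested on the dim TPSG1.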
